A study of Rattus norvegicus with 2 samples.

How the data were processed

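RNA from cultured primary neonatal rat cardiomyocytes was measured on Affymetrix whole-transcript arrays, 1 for vehicle and 1 for LPS at 100 ng/mL, both 24 h after treatment. Whether the RNA of an array came from a single culture or was pooled from several is not given in the sources used here. Per the labels' protocols, total RNA was column-purified, amplified and labelled with the GeneChip WT PLUS kit and biotin. Per the submitters' processing notes, the arrays were processed with RMA in Affymetrix Expression Console 1.4.1. RMA corrects background, sets the distributions of the arrays equal and summarises the probes of a cluster by median polish. The number of arrays processed together, the scaling after RMA and the annotation version are not given in the sources used here, nor is a genome build, so no coordinates are printed.

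The deposited values are intensities on a linear scale, 1 per transcript cluster and array. RMA usually returns log2 values, but the deposited intensities ran from 4.89 to 526444 on the vehicle array and from 4.49 to 547546 on the LPS array. Their log2 values had at most 6 decimals for 100% of clusters (tolerance 5e-08), so they look like antilogs of log2 output. The scanner limit of 16 bits, 65535, was exceeded by 1364 clusters with vehicle and 1461 with LPS, so the scale is not raw scanner brightness and its absolute level has no known unit. The median was 49.3 on both arrays and the 75th percentiles were 232 and 237. The 2 values were exactly identical in 46277 of 68842 clusters (67.2%). The share was 86.1% in the lowest of 10 level bins and 14.1% in the highest. The number of arrays limits the precision, since 1 array per group gives no error.

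Log2 of the intensities was taken with no pseudocount and no further normalization. Of the clusters, 23446 had 1 gene symbol, 505 several and 44891 none in the platform table. Symbols were updated through Entrez IDs against the RefSeq gene table of assembly GRCr8, where 22077 matched and 1 symbol was replaced, and no gene was named from a cluster with several symbols. For the 1182 genes with several clusters, the cluster with the highest mean of both arrays was used. A gene entered the comparison when the higher of its 2 values was at or above the median cluster mean, 49.3 (5.62 on the log2 scale), which left 14420 genes. Across these genes, which are not independent replicates, Pearson's r between the arrays was 0.966, and 76.6% differed by less than 1.2-fold.

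No test was run. Genes were counted at a fixed size of 2-fold. The 39 gene lists, the floor, the size, the rule for named genes and the main alternative settings were fixed before the data were examined. Each list with at least 3 members above the floor is described by its median log2 difference and by the percentile of that median among 10000 random lists of the same size, drawn within 10 bins of mean level, with equal values counted as mid-ranks. A percentile of 100 or 0 means above or below all random lists. Because many genes had identical values, the medians of random lists lay at or near 0. For some lists their central 95% ran from 0 to 0, so even a very small median can stand at an extreme percentile. The percentile therefore does not measure the size of a difference. Several lists share genes, such as the HIF target and glycolysis lists. The lists describe these arrays only.

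Genes were named by a rule with 3 parts. The first took the 15 largest positive and the 15 largest negative differences, leaving out predicted, olfactory, vomeronasal and small RNA genes. The second took up to 4 members of each list with the largest absolute difference, and up to 2 with the highest level where the list median was under 2-fold. The third was a set of HIF, hypoxia, lipid and cardiac genes named for the study's topic. The rule gave 207 genes. Where raising values under 236, the 75th percentile of cluster means, to that level moved the fold of a gene named in the report by over 1.5 times, the raised value is also given.

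Alternatives were centring on the median, removal of a loess trend on level (span 0.3), the mean over the clusters of a gene, no floor, a floor at 236, sizes of 1.5-fold and 3-fold, unmatched random lists and the mean in place of the median. The loess was run with 0 robust iterations, because with most differences exactly 0 the robust weights broke down. That setting was chosen after a first robust run had been seen. In the highest of 10 level bins the trend had a median of 0.12, above the median difference of 0.05. Its removal may therefore take out more than an offset between the arrays, and small changes of sign after it are uncertain. Raising low values, leaving out identical values and leaving glycolysis genes out of the HIF target list were added after the data were seen. So were the tolerances used to say that a value moved: for lists the larger of 0.1 log2 and 0.5 times the central 95% range of random medians, for genes the 84th percentile of absolute differences. The choice of 10 lists as main results was also made then.

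The counting and list procedures were tested on simulated data for the comparison of LPS with vehicle, with no noise for most genes and an assumed noise well below the 2-fold size for the rest. Among 14420 genes, 200 were given a log2 change of 1.5, and 100% were recovered with 0 false genes. A simulated list of 30 genes shifted by 0.5 gave a median of 0.5 at percentile 100, and an unshifted list was at percentile 50.0. This checks the computation and says nothing of how often a 2-fold difference between single arrays arises by chance. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.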

Results

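Gene expression was measured in primary cardiomyocytes from neonatal SD rats, heart muscle cells kept in culture for several days before treatment. Lipopolysaccharide (LPS), a bacterial outer membrane component recognised by Toll-like receptor 4, was given at 100 ng/mL, and RNA was taken 24 h later. Control cells received vehicle and were also sampled at 24 h. Some markers of other cell types were high with vehicle too, such as Col1a1 of fibroblasts at 166482 and Cd68 of macrophages at 17875. Other macrophage markers were lower there, such as Msr1 at 2868, C1qb at 354 and Adgre1 at 64.4. Which cells of the cultures a difference came from was not tested. Each group was hybridised to 1 array, so no spread between samples could be estimated. Differences are therefore given as LPS minus vehicle on the log2 scale, or as fold, with no test, and describe these 2 arrays. The series title places the comparison in the study of septic cardiomyopathy, phospholipid metabolism and hypoxia-inducible factor 1 alpha (HIF-1α). The arrays held 68842 transcript clusters, of which 23446 carried 1 gene symbol, giving 22093 genes. The median intensity was 49.3 on both arrays, and 14420 genes reached this floor on at least 1 of them. The values of the 2 arrays were exactly identical for 45.9% of the genes above the floor.

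More genes were higher than lower on the LPS array by at least 2-fold, and genes of inflammation and lipid mediators were among those with the largest differences. Il1b (Entrez 24494), which encodes the cytokine interleukin-1 beta, had an intensity of 52.9 with vehicle and 51996 with LPS, 984-fold higher. Pla2g2a (Entrez 29692), a secreted phospholipase A2, was 982-fold higher, at 44.9 and 44095. Enpp2, which encodes autotaxin, the enzyme that forms lysophosphatidic acid, was 857-fold higher, at 64.6 and 55386. Nos2, the inducible nitric oxide synthase, was 303-fold higher, and a second cluster for the gene was 141-fold higher. Of the 14420 genes, 532 were at least 2-fold higher and 379 at least 2-fold lower, while 13509 lay between. At least 4-fold differences numbered 236 higher and 56 lower, and at least 10-fold differences 87 higher and 12 lower. At least 100-fold differences numbered 13 higher and 0 lower.

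**Figure D1:**
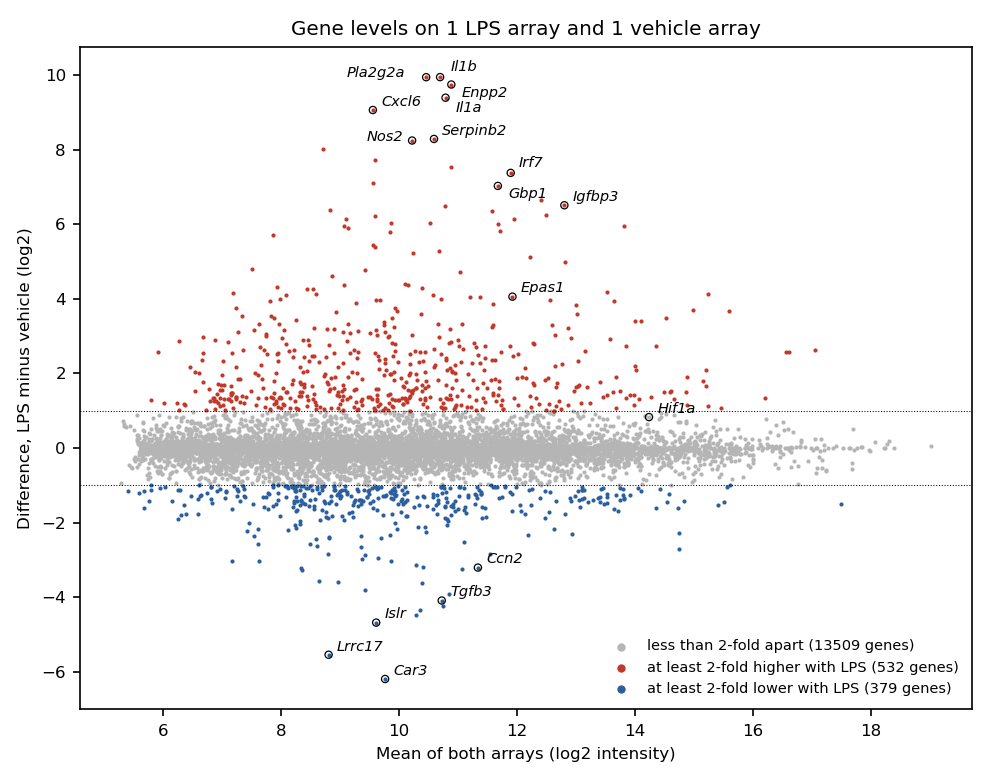
Each point is 1 of 14420 genes, with the mean log2 intensity of both arrays on the x axis and the log2 difference, LPS minus vehicle, on the y axis, and dotted lines at the 2-fold size. Red points are the 532 genes at least 2-fold higher, blue points the 379 at least 2-fold lower and grey points the 13509 between, with Il1b at 9.94 and Car3 at -6.20 among the circled genes.

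The chemokine Cxcl6 was 534-fold higher, Il1a 671-fold, the protease inhibitor Serpinb2 312-fold, Cxcl2 258-fold and Ccl6 213-fold. The immune receptor Slamf7 was 186-fold higher, the interferon regulatory factor Irf7 166-fold, Adgre1 137-fold, the guanylate-binding protein Gbp1 130-fold, Ccl12 99.8-fold and Igfbp3 90.9-fold. Several of these folds rest on vehicle values near the floor. With low values raised to the 75th percentile of cluster means, 236, Il1b was 220-fold higher, Pla2g2a 187-fold, Enpp2 235-fold, Il1a 194-fold, Cxcl6 73.5-fold, Nos2 87.9-fold, its second cluster 32.8-fold, and Cxcl2 28.3-fold. Folds computed in this way are called raised folds, and they were 115 for Serpinb2, 109 for Slamf7 and 47.8 for Ccl6. Of the genes at least 100-fold higher, Cxcl6, Nos2, Cxcl2, Ccl6 and Adgre1 had raised folds under 100.

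Car3, a cytosolic carbonic anhydrase, was the gene with the largest lower value, at 7429 with vehicle and 101 with LPS, 73.3-fold lower. Lrrc17 was 46.7-fold lower, Islr 25.7-fold, the imprinted gene Peg10 22.2-fold, the integrin subunit Itga4 19.0-fold and the growth factor Tgfb3 17.0-fold. The ectonucleotidase Entpd1 was 12.3-fold and the plasminogen activator Plau 11.9-fold lower. The log2 difference of Vsnl1 was -3.80 and that of the cadherin Cdh3 -3.59. The remaining genes of the 15 with the largest lower values were Fabp4, Col6a3, Rgs18, Ccn2 and Gask1b, 9.65-fold to 9.11-fold lower. With low values raised, Car3 was 31.5-fold, Lrrc17 12.9-fold, Islr 16.8-fold, Cdh3 7.33-fold, Plau 5.83-fold, Fabp4 4.28-fold and Rgs18 4.19-fold lower.

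Genes of Toll-like receptor 4 signalling and its NF-κB feedback were higher as a group. Of 28 members above the floor, 15 were at least 2-fold higher and none at least 2-fold lower. Lbp, the LPS-binding protein, was 76.3-fold higher, the feedback inhibitors Tnfaip3 26.2-fold and Nfkbia 12.7-fold, and Irak3 9.87-fold. Tlr4 itself was 1.09-fold higher, at 518 and 565. The list median was 1.2, at percentile 100 of 10000 random lists matched on level. Over the same arrays, 20 macrophage markers had a median of -0.10 and a mean of 0.090, with members in both directions, 3 at least 2-fold higher, including Adgre1, and 4 lower.

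Cytokines and chemokines showed the largest list median, 2.90, with 24 of 31 members at least 2-fold higher and none at least 2-fold lower. Interferon-stimulated genes had a median of 2.82, with 32 of 38 at least 2-fold higher and none lower by that size. With no floor the order of these 2 lists was reversed, at 2.77 for cytokines and 2.82 for interferon genes. Oasl was 82.5-fold higher, with a raised fold of 17.5, and Gbp5 56.4-fold higher, beside Irf7 and Gbp1. Class I antigen processing genes had a median of 1.12 over 13 members, of which 8 were at least 2-fold higher. Psmb8 was 8.74-fold higher and its second cluster 3.65-fold, or 1.07-fold with low values raised, the loading factor Tapbp was 4.53-fold higher, Psmb9 4.06-fold and B2m, the light chain of class I molecules, 3.49-fold. Each of these 3 medians was at percentile 100. The interferon median was 1.58 with low values raised.

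Acute-phase and complement genes had a median of 2.05 over 18 members, with 12 at least 2-fold higher and 1 at least 2-fold lower. Complement component C3 was 61.4-fold higher, the siderophore-binding Lcn2 43.8-fold, C1s 34.8-fold and the haem-binding Hpx 20.1-fold. Their raised folds were 17.7 for C3, 21.0 for Lcn2 and 4.60 for Hpx, while C1s kept its fold. C1qb, a complement gene typical of macrophages, was the member at least 2-fold lower, at 4.07-fold, but its raised fold was below 2, with a log2 difference of -0.59. Adhesion molecules had a median of 1.68 over 8 members, 5 of them at least 2-fold higher. Vcam1 was 63.6-fold higher, Icam1 10.6-fold and Cd44 4.13-fold. Selp was 11.5-fold higher, from a vehicle value of 47.7, with a raised fold of 2.33. Both medians were at percentile 100. With rows of a gene averaged, the acute-phase median was 1.27, and with no floor it was 1.15.

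Hif1a (Entrez 29560), the gene of the HIF-1α subunit, was 1.77-fold higher, at 14533 with vehicle and 25774 with LPS. Epas1 (Entrez 29452), which encodes HIF-2α, was 16.6-fold higher, at 952 and 15833. Among their regulators, the prolyl hydroxylase gene Egln1 was 1.62-fold higher, Vhl 1.36-fold, and Egln3 had identical values of 19197. Arnt, the shared partner subunit, was 1.02-fold higher and Hsp90ab1 1.09-fold, and both were slightly lower, at -0.05 and -0.02 log2, once a loess trend on level was removed. Over 18 HIF subunits and regulators the median was 0, at percentile 59.7, with Epas1 the 1 member at least 2-fold higher. These are transcript levels, and HIF protein was not measured.

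Genes induced by hypoxia through HIF were higher as a group, with 38 of 46 higher, 4 lower and 4 identical. Of these, 15 were at least 2-fold higher. Aldoc, a glycolytic aldolase, was 9.94-fold higher, the vasodilator peptide gene Adm 8.11-fold, the collagen prolyl hydroxylase P4ha2 6.25-fold and the glucose transporter Slc2a1 4.22-fold. Hk2 was 3.55-fold higher, the mitophagy receptor Bnip3 3.37-fold, Pfkl 3.03-fold and Vegfa 2.67-fold. Pdk1, which restrains pyruvate dehydrogenase, was 1.44-fold and Ldha 1.29-fold higher. The member at least 2-fold lower was Anln, a cytokinesis gene named after its value was seen, at -1.64. The list median was 0.58, at percentile 100.

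Of 12 genes reported as targets of both HIF and NF-κB, 8 were at least 2-fold higher and none lower by that size. The median was 1.86, at percentile 100, and the members include Il1b and Nos2. Ptgs2, the inducible cyclooxygenase, was 14.2-fold higher and the transferrin receptor Tfrc 3.12-fold.

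**Figure D2:**
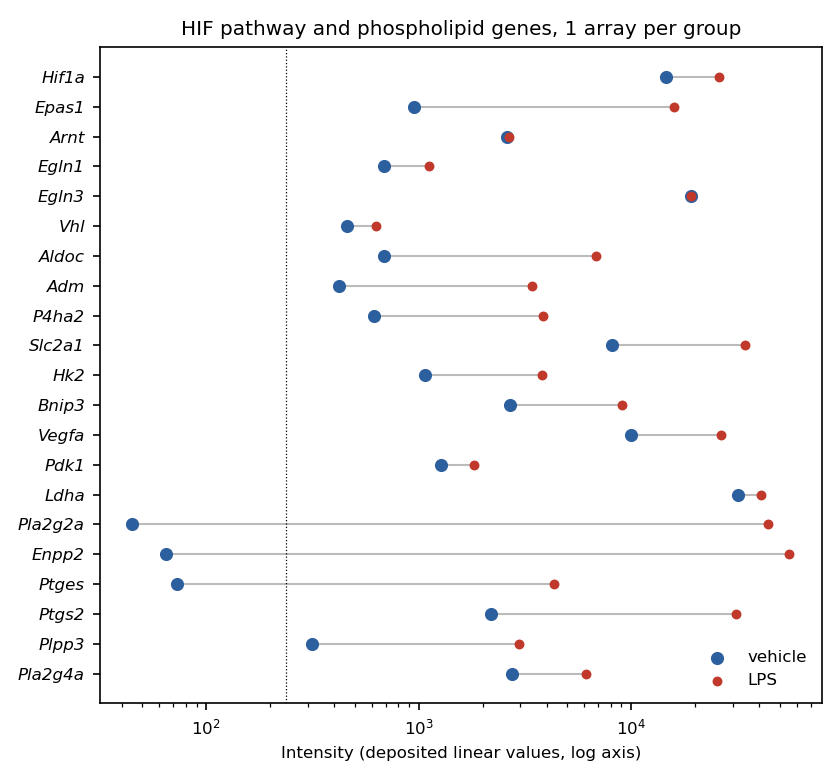
Each line joins the intensity of 1 gene on the vehicle array (blue) and on the LPS array (red), on a log axis of the deposited linear values, with a dotted line at 236, the 75th percentile of cluster means. Epas1, Pla2g2a and Enpp2 lie far apart on the arrays, while Arnt is close to its vehicle value and the points of Egln3 coincide.

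Glycolysis genes had a small positive median of 0.26 over 37 members, at percentile 100. Of these, 22 were higher, 6 lower and 9 identical, and 6 were at least 2-fold higher. Aldoc, Slc2a1, Hk2 and Pfkl were the largest, while Gapdh was identical, Pgk1 was 1.26-fold and Gpi 1.39-fold higher. The median was 0.059 with low values raised.

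Nuclear-encoded respiratory chain genes lay slightly lower on the LPS array. For complex I, 25 of 34 were lower, 1 higher and 8 identical, with a median of -0.06 at percentile 1.30. Ndufb6 was 1.42-fold and Ndufb10 1.35-fold lower, and none reached 2-fold. Complexes II to IV with cytochrome c had a median of -0.10 over 26 genes, at percentile 0.97, with Cycs 1.24-fold and Cox6a1 1.22-fold lower. The cluster used for Cycs had no Entrez ID, and a second cluster for the gene was at -0.46 log2. ATP synthase genes had a median of -0.05 over 16 members, at percentile 15.6, with Atp5mc2 1.38-fold lower. When the mean replaced the median, complex I stood at percentile 11.9 and complexes II to IV at 17.1, inside the central 95% of random lists. The same held with identical values left out, at percentiles 24.8 and 12.7.

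Of 18 tricarboxylic acid cycle genes, 13 were lower, 4 higher and 1 identical, with a median of -0.05 at percentile 14.2. Acod1, which makes itaconate from a cycle intermediate, was 52.4-fold higher, from 32.0 to 1679, or 7.11-fold with low values raised. Dlst was 1.24-fold and Mdh1 1.17-fold lower. The mean of the list was 0.25, opposite in sign to its median. It includes Acod1 at 5.71 log2, while the other 17 members lay within 2-fold.

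Over 25 genes of mitochondrial biogenesis, dynamics and mitophagy, the median was 0 at percentile 56.3, and Bnip3 was the 1 member at least 2-fold higher. Ppargc1a, a coactivator of mitochondrial biogenesis, was 1.55-fold lower, at 2463 and 1594, and Ppara was 1.69-fold higher. Fatty acid uptake and beta-oxidation had a median of -0.04 over 30 genes, at percentile 3.15. Fabp4 was 9.65-fold lower, or 4.28-fold with low values raised, and the lipase Lpl 2.55-fold lower, while Acsl1 was 2.05-fold and Acsl4 1.91-fold higher.

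Among phospholipid genes, a few enzymes differed strongly and most members did not. Beside Pla2g2a, the prostaglandin E synthase gene Ptges was 59.6-fold higher, or 18.4-fold with low values raised, Ptgs2 was 14.2-fold higher, and the cytosolic phospholipase Pla2g4a was 2.23-fold higher. These were the 4 of 35 phospholipase and eicosanoid genes at least 2-fold higher, and 1 was lower by that size. The list median was 0.0091, at percentile 99.94, and -0.01 after removal of the loess trend. The central 95% of random lists ran from 0 to 0 here, so this percentile does not show a shift of the list. With no floor, the percentile was 50.

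For phospholipid synthesis and remodelling, the median was 0 over 48 genes, at percentile 51.0, with 2 at least 2-fold higher. Plpp3, a lipid phosphate phosphatase, was 9.40-fold and the scramblase Plscr1 3.30-fold higher. Lclat1 was 1.80-fold and Lpcat4 1.76-fold lower. The lysophosphatidic acid and sphingolipid signalling list had a median of 0 over 22 genes, at percentile 53.0, with 4 at least 2-fold higher. Its mean was 0.60, at percentile 99.7, and with the floor at 236 its median was 0.12, also at percentile 99.7. That mean includes Enpp2 at 9.74 log2, while 10 of the 22 members were identical. Enpp2 was accompanied by the receptor Lpar4 at 3.40-fold, the glucosylceramide synthase Ugcg at 3.23-fold and the receptor S1pr3 at 2.17-fold.

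Cardiomyocyte sarcomere genes were lower as a group, with 22 of 28 lower, 2 higher and 4 identical, and a median of -0.45 at percentile 0. Myl4, an atrial light chain, was 2.85-fold lower, Tcap 2.19-fold, Nexn 1.97-fold and the cardiac actin Actc1 1.49-fold. Myh7 was identical on both arrays. Myh6 shared its cluster with a microRNA gene, so it was not analysed here. Smooth muscle and pericyte markers also had a negative median, -0.75, with 3 of 12 at least 2-fold higher and 4 lower. That median was smaller in size with low values raised.

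Fetal and stress genes of the cardiomyocyte had a median of -0.54 over 16 members, at percentile 0, with 5 at least 2-fold lower and none higher by that size. Ccn2 was 9.24-fold and Ccn1 4.96-fold lower, both matricellular genes, and skeletal actin Acta1 was 2.14-fold lower. The natriuretic peptide gene Nppb was 1.48-fold lower. Nppa was 1.13-fold higher, a log2 difference of 0.18 that was -0.01 after removal of the loess trend. Calcium handling, ion channel and adrenergic genes had a median of 0 over 44 members, at percentile 52.2, and none differed 2-fold. Atp2a2, the sarcoplasmic calcium pump, was 1.27-fold higher, Adrb1 1.79-fold and Grk5 1.75-fold, and Adra1a was 1.68-fold lower.

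Cell cycle and DNA replication genes were lower almost throughout, with 37 of 38 lower and 1 identical. Of these, 26 were at least 2-fold lower. Thymidine kinase Tk1 was 4.15-fold lower, the replication helicase subunits Mcm5 3.71-fold and Mcm6 3.30-fold, and the mitotic kinase Plk1 3.41-fold. The median was -1.37, at percentile 0. Beside these, smooth muscle and pericyte markers had a median of -0.75 at percentile 0, smaller in size with low values raised. Of these 12 markers, 3 were at least 2-fold higher and 4 lower. Fibroblast markers had a median of -0.10 at percentile 4.07, with Thy1 3.87-fold lower and Dcn 12.8-fold higher.

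**Figure D3:**
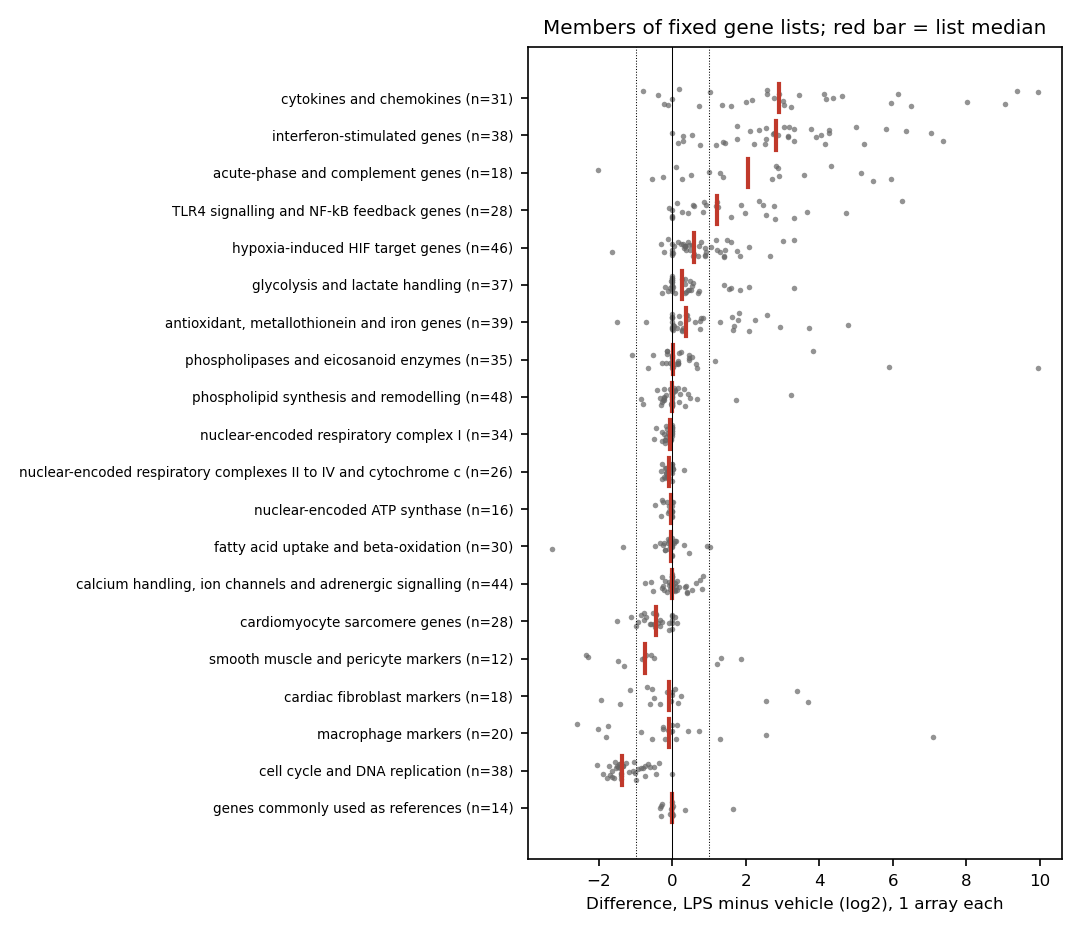
Each grey point is 1 gene above the floor in 1 of 20 gene lists, placed by its log2 difference, LPS minus vehicle, with a red bar at the list median and dotted lines at the 2-fold size. The medians reach 2.90 for cytokines and chemokines and -1.37 for cell cycle genes, and the reference genes have a median of 0.

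Antioxidant, metallothionein and iron genes had a median of 0.37 over 39 members, at percentile 100, with 12 at least 2-fold higher and 1 lower. The metalloreductase Steap4 was 27.5-fold higher, with a raised fold of 15.3, the metallothioneins Mt1 13.1-fold and Mt2A 5.99-fold, and the mitochondrial superoxide dismutase Sod2 7.55-fold. A second cluster for Mt1 was 3.06-fold higher, with a raised fold of 1.12. In nitric oxide and arginine metabolism, 5 of 14 genes were at least 2-fold higher and 1 lower, with a median of 0 at percentile 55.9. Its mean was 1.30, at percentile 100, and with the floor at 236 its median was 0.07, at percentile 98.7. That mean includes Nos2 at 8.24 log2 and Ass1 at 6.21 log2, while 3 of the 14 members were identical. Ass1, which regenerates arginine, was 73.8-fold higher, the arginine transporter Slc7a2 6.70-fold and the cofactor enzyme Gch1 4.52-fold. The raised folds were 28.1 for Ass1 and 2.86 for Gch1.

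Cell death genes had a median of 0.15 over 28 members, at percentile 100, with 6 at least 2-fold higher. Tnfrsf1b was 5.52-fold, the death receptor Fas 3.56-fold, the inflammasome sensor Nlrp3 3.25-fold and Ripk2 3.20-fold higher. With low values raised, the median was 0.045 and both Nlrp3 values equalled the raised level. Unfolded protein response genes had a median of -0.0049 over 23 members, at percentile 15.3. The member at least 2-fold lower was Chac1, at 2.24-fold, but both of its values were under 236, so its raised difference was 0. Ddit3 was 1.81-fold higher. Cholesterol synthesis had a median of 0 over 20 genes, at percentile 55.7, with the sterol exporters Abcg1 2.44-fold and Abca1 1.93-fold higher.

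Markers of other cell types went in both directions. Of 18 fibroblast markers, 3 were at least 2-fold higher and 3 lower, with a median of -0.10 at percentile 4.07 and a mean of 0.15. The proteoglycan Dcn was 12.8-fold, the receptor Pdgfra 10.5-fold and Lum 5.89-fold higher, while Thy1 was 3.87-fold and Vim 1.46-fold lower. Smooth muscle and pericyte markers had a median of -0.75 over 12 genes, at percentile 0, with 3 at least 2-fold higher and 4 lower. Smtn was 5.09-fold, Tagln 4.88-fold and Acta2 2.81-fold lower, and Abcc9 was 3.66-fold higher. Their median was -0.36 with low values raised.

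Macrophage markers had a median of -0.10 over 20 genes, at percentile 0.28, with 3 at least 2-fold higher and 4 lower. Adgre1, which encodes the F4/80 antigen, was 137-fold higher, or 37.3-fold with low values raised, and Fcgr3a 5.82-fold higher, with a raised log2 difference of 1.32. Clec4a3 was lower, with a log2 difference of -2.58, or -1.02 with low values raised, Cd68 was 1.10-fold lower and Msr1 1.33-fold higher. The mean was 0.090, opposite in sign to the median, and it includes Adgre1 at 7.09 log2, while the lowest member was at -2.58. Endothelial markers had a median of 0 over 12 genes, at percentile 51.4, with Kdr 2.76-fold higher and Fabp4 lower. With the floor at 236 the endothelial median was -0.49, at percentile 0.81.

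Collagen and matrix remodelling genes had a median of -0.02 over 32 members, at percentile 10.9, with 5 at least 2-fold higher and 6 lower, and a mean of 0.09. The proteases Mmp9, Mmp13 and Mmp3 were 71.0-fold, 27.6-fold and 6.17-fold higher. The raised folds were 4.03 for Mmp13 and 2.20 for Mmp3, while Mmp9 kept its fold. Spp1, which encodes osteopontin, was 6.51-fold lower and Col1a1 1.25-fold lower, while Fn1 was 1.42-fold higher. The Schwann cell and neuron list had a median of 0 over 5 genes, at percentile 50.7, with Tubb3, a beta-tubulin gene, 4.33-fold lower. Elavl4, Mbp and Erbb3 were near the floor, at 55.8, 54.5 and 49.3 with vehicle, so the list says little of such cells. Epicardial markers had a median of 0 over 10 genes, at percentile 52.2, and none differed 2-fold.

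Above the floor were 1 of 12 neutrophil markers, 2 of 14 lymphocyte markers and 2 of 8 erythroid markers, too few for a median. Fcnb, Cd79a, Hba-a1 and Hbb had identical values, and Cd4 was 1.07-fold lower. Genes commonly used as references had a median of 0 over 14 members, at percentile 67.3, and -0.15 after removal of the loess trend. Gapdh was identical, Ppia was 1.24-fold lower and Tfrc, the 1 member at least 2-fold higher, is also an iron gene.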

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

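Clusters without a single gene symbol lie outside the gene comparison, and they too held differences above the vehicle array. Of 19586 such clusters above the floor, 386 were at least 2-fold higher on the LPS array and 156 at least 2-fold lower. Of the 386, 374 had no symbol in the platform table and 12 had several. The largest fold among those with no symbol was 67.0, and the lowest log2 difference was -5.78. With values under 236 raised to that level, a setting chosen after the data were seen, the clusters with these 2 values were at 19.1-fold and -3.15, and 296 clusters were at least 2-fold higher and 88 lower. Their genes were not analysed here, so some of these clusters may belong to genes named above, and near-identical clusters can repeat the same transcript.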

How the results depend on the processing

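No paired analysis was possible because each group had 1 array, and for the same reason no array could be left out. Raising low values, leaving out identical values and leaving out glycolysis genes were chosen after the data were seen. The count of genes higher was 872 at 1.5-fold and 317 at 3-fold, and the count lower 818 and 113, as the size itself sets. The other settings gave 437 to 532 higher and 303 to 413 lower. Medians moved as follows, and the cause was not tested, though a mean weighs single large members more than a median does. With the mean in place of the median, TLR4 and NF-κB genes were at 1.59, cytokines 3.33, interferon genes 2.96, HIF targets 0.77, glycolysis 0.46, phospholipases 0.63 and cell cycle genes -1.21, and macrophage markers reversed to 0.090 at percentile 68.7. Complex I was then at percentile 11.9. With identical values left out, TLR4 and NF-κB genes were at 1.41, HIF targets 0.71, glycolysis 0.40 and phospholipases 0.16, with complex I at percentile 24.8 and macrophage markers at 4.68. With the floor at 236, cytokines were at 3.79, interferon genes 3.16, HIF targets 0.70 and phospholipases 0.16, with complex I at percentile 2.53. With low values raised, cytokines were at 2.29, interferon genes 1.58, glycolysis 0.059 and cell cycle genes -1.22, and phospholipases at percentile 50.03. With no floor, cytokines were at 2.77 and phospholipases at percentile 50.005. After loess, HIF targets were at 0.46, and without glycolysis genes at 0.83. The TLR4, cytokine, interferon, HIF target and glycolysis lists stayed at percentiles of 99.8 to 100, and the sarcomere and cell cycle lists at 0, under every setting run. Among the other lists, with each list counted once per setting, 48 medians moved and 159 did not. With the mean, the tricarboxylic acid cycle, fibroblast and matrix lists took the other sign, at 0.25, 0.15 and 0.087. Over all these other lists, again counted once per setting, 16 percentiles left the central 95% and 2 entered it. Of the 207 named genes, 38 moved with low values raised, and 3 with several clusters averaged: Nos2 to 7.69, Mt1 to 2.66 and Psmb8 to 2.5. The loess trend reached 0.20, and 12 named genes with differences of at most 0.18 took the other sign. Low signal limits the folds of genes near the floor.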

Other observations

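The gene families here and the tests of identical values and of a smaller cardiomyocyte share were chosen after the data were seen, while the test of a larger macrophage share (for a pattern named later) and that of HIF targets were written before their results. In the rat major histocompatibility complex, 8 of 18 RT1 genes above the floor were at least 2-fold higher on the LPS array, among them RT1-S3 at 2.96, RT1-CE13 at 2.61 and RT1-CE4 at 2.55 (log2), which are class I genes. RT1-DMa and RT1-DMb, which load peptides on class II molecules, were lower, at -1.83 and -1.56. Near-identical RT1 copies can share probes, so single members are uncertain. Of 9 guanylate-binding protein genes and pseudogenes, 8 were at least 2-fold higher, and of 8 Pilrb genes 6 were. The loess trend, at most 0.20, is smaller than any of these differences.

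Of 15 histone genes with symbols starting with Hist, 6 were at least 2-fold lower and none higher by that size, with Hist1h4b at -1.78, while 4 were identical and Hist1h2bq was at 0.46. All 9 beta-tubulin genes above the floor were lower, 3 of them at least 2-fold. Of 23 cytochrome P450 genes, 5 were at least 2-fold higher, with Cyp7b1, which hydroxylates oxysterols, at 6.02 (4.99 with low values raised), Cyp4f5 at 2.36 and Cyp4f37 at 2.22. Outside the naming rule, Il6 was 70.8-fold and Tnf 24.6-fold higher, or 19.6-fold and 9.79-fold with low values raised, and Mki67 was 2.54-fold lower.

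Identical values were found in 67.2% of clusters. A candidate explanation is that RMA summarised these arrays together with another, since median polish over 3 arrays can return the same value for a pair. In simulated unchanged sets, 3 arrays gave identical values in 29.5% to 89.7% of sets over 5 to 40 probes with averaged middle values, a range that holds the observed share, and a true difference of 0.3 came out as 0.16 to 0.22. Over 2 arrays the share was 0 to 26.8%, depending on how the middle value is taken, and simulated settings exclude nothing, so this stays open. No biological explanation was tested, and small differences may be understated. In the simulation over 3 arrays with averaged middle values, a true difference of 1 came out as 0.87 to 0.93. Under that explanation, genes close to the 2-fold size could fall below it.

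Adgre1, a macrophage marker, was 137-fold higher, and a larger share of macrophages in the LPS-treated cells would raise the others too, but the 19 other markers had a median of -0.13, with 6 higher, 11 lower and 2 identical. This argues against it as the whole cause, although LPS may itself lower some of these markers. A smaller share of cardiomyocytes would raise every other type alike, by about the 5.22 log2 of Adgre1 with low values raised. The fibroblast, endothelial and smooth muscle medians were -0.10, 0 and -0.75, at most 1.44 with 1 SD of the members added. A first bound, which also needed a macrophage median above 0, was not met, and the bound used was set afterwards. Col1a1 was already at 166482 with vehicle, where the highest intensity was 526444, so such a rise could hardly have been seen. The SD of members is also no error of a change in cell share, so no conclusion on that share is drawn. An effect of LPS on the gene remains untested, since each group had 1 array.

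HIF targets were higher, with Epas1 16.6-fold and Hif1a 1.77-fold higher. An offset between the arrays at high levels could raise such genes, but after removal of the loess trend the list median was 0.46, with random lists between -0.14 and -0.05. The trend may remove more than an offset, since in the highest level bin it lay above the median difference. The list stayed above the random lists all the same, which argues against the offset as the whole cause. Effects of LPS, of HIF and of NF-κB, which shares targets with HIF, cannot be separated with these arrays, and culture differences stay open.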
